A study of Mus musculus with 24 samples.

How the data were processed

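Ribosome profiling was done on 24 livers of male F1 C57BL6J/FVBN mice, and the labels place the libraries in 6 groups of 4. Liver lysates were treated with cycloheximide and digested with RNase I, and the mRNA fragments that ribosomes had protected were sequenced after ribosomal RNA depletion, per the labels' protocols. The labels state that mRNA sequencing was done on the same livers. Those libraries were not part of the data used here, so a change in ribosome footprints is not split into a change in mRNA level and a change in translation per mRNA.

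The deposited gene table holds whole read counts per Ensembl gene and library, with no normalization, as its values show. The deposited table of open reading frames (ORFs) holds whole counts of P-sites, the position of the ribosome's peptidyl site, per ORF and library. Per the submitters' processing notes the tools were Trimmomatic 0.39, STAR 2.7.0f and 2.7.8a, featureCounts, Subread 1.6.4, cutadapt 3.4 and Bowtie2 2.4.2, with genome build GRCm38.p6. Which tool made which table, the annotation release, the treatment of reads that fit several genes, the use of strand and the rule that selected the ORFs are not given in the sources used here. Near-identical paralogs are therefore uncertain one by one, which concerns the Cyp2b, Cyp2c, Cyp3a, Cyp4a, Mup, Sult, Fmo, Serpina and amylase families. The length that the gene table lists is the genomic span with introns, judged by its size for genes with long introns. The ORF table names a transcript, a start and an end and no gene, so no ORF is given a gene name. Its pooled column was 102% of the sum of the libraries and was equal to that sum in 648 of 22590 ORFs, and it entered no test.

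Of the 22429 genes in the table, 13 had no symbol, 21674 were matched by symbol to the RefSeq gene table of the mouse, 36 by an older symbol and 13 as mitochondrial genes, and 706 stayed unmatched. The match served the gene type alone, and gene names are the symbols in the deposited table. No library or gene was left out before the filter on low counts. Total counts per library ran from 13366558 to 27084259.

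Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 6 groups, which left 12211, library sizes were scaled by TMM, and a robust quasi-likelihood model was fitted over all 24 libraries with 1 term per group and no covariate, with 18 residual degrees of freedom. All groups shared 1 estimate of the spread, and the biological coefficient of variation was 24.2%. Each of 7 contrasts was tested 2-sided with the quasi-likelihood F test. Adjusted p is the Benjamini-Hochberg value of that test over all genes unless another test is named, the threshold was 0.05, and no fold threshold was set. Log2 changes are given with a standard error derived from the test, the size of the change divided by the square root of its F statistic. Abundances are CPM, counts scaled by effective library size, as mean ± SD over the 4 libraries of a group. The prior count of log2 CPM was 2. The mutant response minus the wild-type response to restriction was tested as an interaction contrast.

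A total of 41 gene lists, 29 of pathways or expression patterns and 12 of cell types, were written down from general knowledge before the data were examined, as were the comparisons, the tests and the rule for naming genes. The 38 lists with 5 or more tested members were compared with all other genes by camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of each comparison. The same test with a correlation estimated from the data is given beside it. The count of changed members is given over all genes and adjusted over the list alone. Genes named for size were the 6 largest rises and the 6 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and every library of one group above every library of the other, without gene models and pseudogenes. Not every gene that this rule picks is given. The separation of libraries was not asked for in the interaction. Up to 4 members with the smallest adjusted p were available per described list, and Ercc1, Igf1, Cdkn1a and Gdf15 were followed in all contrasts. The part of the rule on ORF names could not be applied.

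For the length trend, tested protein-coding genes were put in 5 groups of equal size by genomic span. Per library, the mean log2 CPM of the longest group minus that of the shortest was compared by an exact 2-sided permutation test over all 70 assignments of 4 against 4 libraries. Pairs of comparisons were set beside each other by the correlation and covariance of log2 changes across genes and by shared calls. Unchanged groups, the shared one included, were simulated from the mean levels of the shared group. The shared group was also split into 2 and 2 libraries. P-site counts of 18344 ORFs that passed the same filter were tested in the same way as genes.

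The gene, ORF, list and length tests were tested on simulated data first, for the progeroid comparison, as was the correlation of 2 comparisons. The interaction, the splits, the score tests and the correlations within groups were not. With 200 changed genes planted among 12000 in a simulation of the progeroid comparison, 11.9% of the 1.5-fold, 74.6% of the 2-fold and 100% of the 4-fold changes were recovered, with 7 false calls among 131. Among 18072 ORFs the shares were 11.9%, 56.7% and 93.9%, with 8 false calls among 116. A planted list reached an adjusted p of 1.96e-68 and 0 of 38 unchanged lists passed in camera. The simulated genes were drawn independently of each other. This simulation therefore cannot show how many false list calls the preset correlation gives where genes of a list vary together. A planted length slope of -0.1 gave a difference of -0.49 (exact permutation p = 0.0286), and no slope gave 0.00717 (exact permutation p = 0.229).

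Alternatives fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a filter of 50 counts in 4 libraries, protein-coding genes alone, the compared groups alone, the replicate number as a block, the library number as a covariate, and leaving out each library in turn. A fit without 2 libraries, old wild-type replicate 1 with the fewest P-sites per count and restricted wild-type replicate 4, farthest from its group along the first principal component, and a fit with a ribosomal protein score as a covariate were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the tables and drew the figures. Each library is 1 liver, so n counts animals.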

Results

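Footprints of translating ribosomes were counted per gene in the livers of 24 male mice. Wild-type mice and Ercc1 mutants were compared; the mutants carry 1 null and 1 truncated allele of Ercc1, which encodes a subunit of a DNA repair nuclease, and they age early. The 6 groups of 4 were wild types fed ad libitum at 16 weeks and at 104 weeks, and wild types on dietary restriction at 16 weeks, with mutants fed ad libitum at 7 and 16 weeks and on restriction at 16 weeks. Restricted mice received less food from week 7 and 30% less from week 9, and no mouse was fed before collection on the last day. Total counts per library ran from 13366558 to 27084259, and in the 4 old wild types from 13671963 to 16165181. Albumin took 9.92 ± 0.657% of the counts in wild types at 16 weeks, 16.4 ± 1.84% in restricted wild types and 15.5 ± 1.59% in restricted mutants. The first principal component held 24.4% of the variance and the second 17.4%.

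The targeted gene went with the labels. Footprints on Ercc1 were lower in every one of the 12 mutant libraries, with 1 to 15 counts, than in any of the 12 wild-type libraries, with 34 to 110 counts. The level was 2.72 ± 0.727 CPM in wild types at 16 weeks and 0.564 ± 0.232 CPM in mutants of that age (SD, n = 4 each), a log2 change of -2.25 ± 0.41 (adjusted p = 0.000605). Under restriction the values were 2.97 ± 1.3 and 0.44 ± 0.138 CPM, and old wild types had 3.75 ± 0.581 CPM.

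**Figure D1:**
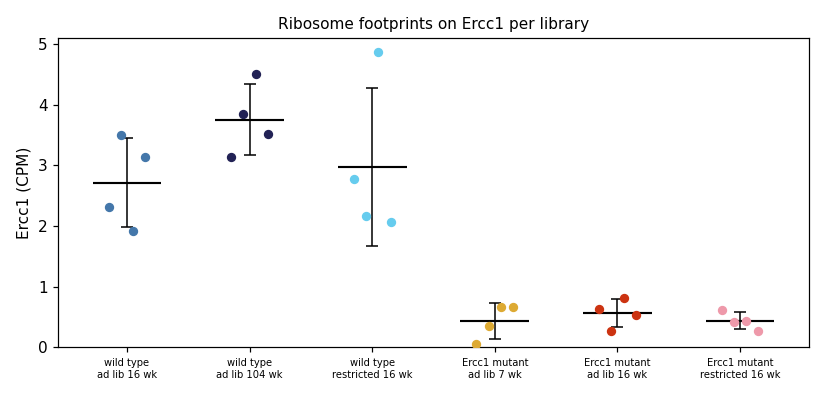
Ercc1 footprints in CPM per library (points) in the 6 groups, with the group mean (line) and SD (bars, n = 4). All 12 mutant libraries lie below all 12 wild-type libraries.

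Mutants fed ad libitum were set against wild types of the same age, 16 weeks, to ask what loss of ERCC1 does to the genes that the liver translates. Footprints on Usp18, which restrains interferon signalling, rose from 0.873 ± 0.142 to 12.6 ± 4.38 CPM (SD, n = 4 each). Those on Scd1, which makes monounsaturated fatty acids, fell from 7296 ± 1694 to 713 ± 304 CPM. Macrophage markers rose and genes that are normally higher in female liver fell. Of 37 fatty acid oxidation, ketogenesis and PPAR alpha target genes 15 fell, a list whose call was lost with an estimated correlation (adjusted p = 0.191). In all, 1310 of 12211 genes changed, 695 up and 615 down, of which 376 and 245 changed more than 2-fold. Without mutant replicate 1 the count was 813, and without wild-type replicate 4 it was 861. A fit of the 8 compared libraries alone called 2138.

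The largest rise in mutants was that of Gpx6, a glutathione peroxidase, at 33.5-fold (log2 5.07 ± 0.39, adjusted p = 3.62e-09). Wild-type replicate 1 had 0.47 CPM and the other 3 had 0.0827 to 0.123 CPM, near the level of 3 counts, and without replicate 1 the log2 change of Gpx6 was 6.02. Cib3, the trefoil factor Tff3, the citrate transporter Slc13a5, the estrogen sulfotransferase Sult1e1 and the sterol enzyme Sqle followed, with folds from 16.6 to 26.1. The largest falls were those of 5 cytochrome P450 genes of the Cyp2b family, led by Cyp2b10 at 39.5-fold lower (log2 -5.30 ± 0.46, adjusted p = 1.96e-07) and with Cyp2b13, Cyp2b9, Cyp2b23 and Cyp2b19 behind it. Without mutant replicate 3 Cyp2b10 was at -6.02 and Cyp2b19 at -4.94, from -3.78 with it. Igf1 had a log2 change of -0.27 ± 0.15 (adjusted p = 0.291), the p53 target Cdkn1a 1.12 ± 0.68 (adjusted p = 0.334) and the stress cytokine Gdf15 1.60 ± 0.56 (adjusted p = 0.0676), and none of the 3 passed.

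Of 35 interferon response genes 20 rose in mutants (31 adjusted over the list alone), among them Ifi27 at 113 ± 8.93 against 50.2 ± 8.31 CPM and Oas1a (log2 2.28 ± 0.28). The list stood above other genes (camera adjusted p = 3.29e-23) and held with an adjusted p = 0.0347 with an estimated correlation. Of 19 macrophage markers 16 rose (17 adjusted over the list alone), such as C1qa, Cd5l (log2 1.32 ± 0.18) and Mpeg1 (log2 1.41 ± 0.20). Their median log2 change was 1.11, and they held as well (adjusted p = 1.16e-18, and 0.0347 with an estimated correlation). Of 6 B and plasma cell markers 2 rose (4 adjusted over the list alone), with a median of 2.21 and Igkc up by 2.59 ± 0.54, and stellate cell markers had a median of 0.45, with Lum and Dcn up. Both of these lists passed camera (adjusted p = 0.00134 and 0.00066) and lost the call with an estimated correlation (adjusted p = 0.191 and 0.464). Of 5 neutrophil markers 2 rose and 1 fell, and the list did not pass (adjusted p = 0.0794).

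Of 37 fatty acid oxidation, ketogenesis and PPAR alpha target genes 15 fell in mutants (24 adjusted over the list alone; adjusted p = 2.9e-10, and 0.191 with an estimated correlation). They include the thiolase Acaa1b (log2 -2.10 ± 0.20) and the fatty acid binding protein Fabp1, at 1627 ± 326 against 4215 ± 823 CPM. Of 24 genes of fatty acid synthesis 8 fell, over all genes and adjusted over the list alone, with Scd1 and Elovl5 (log2 -1.52 ± 0.23) in front (adjusted p = 7.48e-08, and 0.176 with an estimated correlation). Of 26 genes of cholesterol synthesis 9 rose (14 adjusted over the list alone), with Sqle and Msmo1 (log2 1.95 ± 0.39) as examples (adjusted p = 2.58e-07, and 0.34 with an estimated correlation). Of 35 genes of drug metabolism 11 fell and 4 rose (12 and 7 adjusted over the list alone; adjusted p = 3.05e-05, and 0.191 with an estimated correlation). Cyp2c29 dropped to 144 ± 17.8 from 1507 ± 475 CPM.

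Genes higher in female than in male liver fell in these male mutants, 15 of 29 (18 adjusted over the list alone) with 3 risen, and the list held with an estimated correlation (adjusted p = 1.26e-09 and 0.0347). Of 23 genes higher in male liver 8 rose and 2 fell (9 and 3 adjusted over the list alone; adjusted p = 0.00423, and 0.464 with an estimated correlation). The complement gene C6 and Selenbp2 were up, and Cyp4a12a and Cyp4a12b down. Genes of hepatocytes near the central vein had a median of 0.49, with Gulo at log2 1.45 ± 0.16 and the Wnt target Axin2 at 1.81 ± 0.37 (adjusted p = 0.000128, and 0.143 with an estimated correlation). Of 23 targets of p53 9 rose and 2 fell (14 and 2 adjusted over the list alone), led by Phlda3 at log2 3.29 ± 0.59 and Perp at -0.89 ± 0.15 (adjusted p = 0.000517, and 0.273 with an estimated correlation). Oxidative phosphorylation had a median of -0.14 (adjusted p = 0.00134, and 0.51 with an estimated correlation). The lists for NRF2 targets, proliferation, antigen presentation, acute phase, senescence and periportal genes passed camera with adjusted p from 0.012 to 0.0433. They lost the call without 1 or more single libraries and with an estimated correlation (0.191 to 0.761).

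Old wild types at 104 weeks were set against wild types at 16 weeks to describe natural ageing. Footprints on Igkc, an antibody light chain made by plasma cells, rose from 0.884 ± 0.275 to 23.5 ± 7.03 CPM (SD, n = 4 each). Those on Cyp4a10, which oxidises fatty acids, fell from 1023 ± 531 to 46.8 ± 21.7 CPM. Fatty acid oxidation and PPAR alpha target genes, drug metabolism genes and female-biased genes went down, and markers of B cells and neutrophils went up. In all, 1141 genes changed, 580 up and 561 down, of which 287 and 238 changed more than 2-fold, and without young wild-type replicate 4 there were 743.

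The largest rises in old liver were those of Igkc (26.9-fold, log2 4.75 ± 0.56, adjusted p = 7.78e-06) and Ighm, 2 immunoglobulin genes. The early response factors Junb and Maff and the cytokine brake Socs3 followed, with the clock repressor Nr1d1 at 37.9 ± 14.8 against 2.84 ± 2.18 CPM. The largest falls were those of 4 Cyp4a genes, targets of PPAR alpha, with Cyp4a14 32.9-fold lower (log2 -5.04 ± 0.58, adjusted p = 1.13e-05) and Cyp4a10, Cyp4a31 and Cyp4a32 14.8-fold to 21.9-fold lower. G0s2, which inhibits lipolysis, was 13.9-fold lower and Cyp2b10 10.9-fold lower. Without old replicate 1 Junb went from 4.03 to 3.32, Maff from 3.46 to 2.36 and Cyp4a14 to -5.70, without old replicate 2 G0s2 went from -3.79 to -4.53, and without young replicate 1 Nr1d1 went from 3.68 to 4.36. Ercc1 (log2 0.48 ± 0.36, adjusted p = 0.464), Igf1 (0.508), Cdkn1a (0.85) and Gdf15 (0.253) did not pass.

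Of 37 fatty acid oxidation, ketogenesis and PPAR alpha target genes 25 fell with age (30 adjusted over the list alone). Among them were Vnn1 (log2 -2.82 ± 0.29) and the fatty acid transporter Cd36, at 25.0 ± 10.4 against 138 ± 46.5 CPM. The list held with an estimated correlation (adjusted p = 3.65e-40 and 0.00359). Of 29 female-biased genes 13 fell and 1 rose (16 and 1 adjusted over the list alone), such as Cyp3a41b and Cyp3a44 (log2 -2.93 ± 0.26 and -2.94 ± 0.27), and this list held too (adjusted p = 9.72e-22 and 0.000477). Of 35 genes of drug metabolism 16 fell and 2 rose (19 and 4 adjusted over the list alone), with Ces1d (log2 -1.94 ± 0.16) and Cyp3a11 at 264 ± 49.4 against 2144 ± 326 CPM. This list held as well (adjusted p = 1.74e-10, and 0.0448 with an estimated correlation). All 6 tested B and plasma cell markers rose, also when adjusted over the list alone, with a median log2 change of 3.96 (adjusted p = 1.25e-11, and 0.00614 with an estimated correlation). Of 5 neutrophil markers S100a8 and S100a9 rose (3 adjusted over the list alone), by 4.07 ± 0.69 and 3.89 ± 0.57 (adjusted p = 0.000759, and 0.0448 with an estimated correlation). Without young replicate 3 the changes of S100a8 and S100a9 were 4.75 and 5.21.

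The remaining calls on lists in old liver were lost with an estimated correlation. Of 19 macrophage markers 11 rose (14 adjusted over the list alone), with Lyz2 at log2 1.44 ± 0.24 and Marco at 3.08 ± 0.57, or 2.26 without old replicate 1 (adjusted p = 4.27e-08, and 0.209 with an estimated correlation). Of 30 proliferation genes 9 fell and 2 rose (17 and 3 adjusted over the list alone), with Mcm5 and Top2a at -2.12 ± 0.40 and -2.35 ± 0.49 (adjusted p = 4.27e-07, and 0.274 with an estimated correlation). Of 77 genes of oxidative phosphorylation 6 fell (21 adjusted over the list alone), such as Ndufb4 and Sdhd (adjusted p = 7.23e-10, and 0.218 with an estimated correlation). The 13 genes encoded in mitochondria had a median of -1.29 (12 lower adjusted over the list alone; adjusted p = 5.73e-06, and 0.531 with an estimated correlation). Among 27 ATF4 targets Asns rose by 3.57 ± 0.56 and Fgf21 fell, at log2 -2.64 ± 0.57, or -3.42 without old replicate 4. In all 4 were up and 1 down over all genes, and 10 and 2 adjusted over the list alone (adjusted p = 0.00579, and 0.097 with an estimated correlation). Heat shock genes such as Bag3 and acute-phase genes such as Cxcl1 had medians of 0.47 and 0.49 (adjusted p = 0.000127 and 2.73e-05, and 0.531 with an estimated correlation for both). The male-biased list passed with a median of 0.29 (adjusted p = 0.00591, and 0.531 with an estimated correlation). The lists for senescence, cholesterol synthesis, the unfolded protein response, antigen presentation and stellate cells passed with adjusted p from 0.00489 to 0.0207, lost it without 1 or more single libraries and had 0.375 to 0.884 with an estimated correlation.

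Mutants at 16 weeks were set against mutants at 7 weeks to follow the course of the progeroid liver, with growth to adulthood part of the same interval. Footprints on Cyp26a1, which clears retinoic acid, rose from 0.701 ± 0.359 to 6.76 ± 2.97 CPM (SD, n = 4 each), and those on Cyp4a12a, a male-biased enzyme, fell from 683 ± 104 to 276 ± 30.4 CPM. In the fit of all 24 libraries 53 genes changed, of which 30 were up and 23 down, while 1168 had an unadjusted p under 0.05. DESeq2 called 167 and a fit of the 8 compared libraries alone 436. The count of 53 fell to 18 without either replicate 1 or replicate 3 of the 7-week mutants, to 22 without 16-week replicate 4, and to 23 without 7-week replicate 2 or 16-week replicate 1.

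Cyp26a1 was 9.56-fold higher at 16 weeks (log2 3.26 ± 0.37, adjusted p = 5.54e-05), Gpx6 3.64-fold (7.68 ± 3.08 against 2.11 ± 0.32 CPM, adjusted p = 0.00166) and the amino acid transporter subunit Slc3a1 3.50-fold (adjusted p = 0.00469). Fgl1, Adgre4 and Tmem43 also passed, at adjusted p of 0.0302, 0.0379 and 0.0191, and lost the call in 6, 7 and 4 of the 8 fits without 1 library, with adjusted p up to 0.12, 0.174 and 0.105. The largest falls were those of Rgs16 (log2 -2.90 ± 0.51, adjusted p = 0.0105, and 0.0523 without 16-week replicate 4) and the adipokine Serpina12, 5.23-fold lower at 7.5 ± 1.82 against 39.3 ± 12.9 CPM. They were followed by the methyltransferase Inmt, Cyp2c29, Cyp4a12b and Cyp4a12a, the last 2.48-fold lower (adjusted p = 8.26e-05). Igf1, Cdkn1a, Gdf15 and Ercc1 had adjusted p of 0.787, 0.806, 0.832 and 0.864.

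In the course from 7 to 16 weeks 18 lists passed camera and none kept the call with an estimated correlation. Macrophage markers had a median of 0.72, with 2 of 19 up over all genes and 12 adjusted over the list alone (adjusted p = 6.15e-19, and 0.077 with an estimated correlation). Cholesterol synthesis had a median of 0.63, with 12 up adjusted over the list alone (adjusted p = 1.64e-12, and 0.153 with an estimated correlation). Acute-phase genes had one of 0.67, 2 up over all genes and 14 adjusted over the list alone (adjusted p = 1.25e-10, and 0.21 with an estimated correlation). Male-biased genes had a median of -0.40, with the 2 Cyp4a12 genes down over all genes and 8 adjusted over the list alone (adjusted p = 6.68e-08, and 0.121 with an estimated correlation). Drug metabolism had one of -0.27, with Cyp2c29 and Ces2a (log2 -0.77 ± 0.14) among 5 down and 11 adjusted over the list alone (adjusted p = 9.34e-08, and 0.102 with an estimated correlation). Gluconeogenesis had a median of -0.36, B and plasma cell markers one of 1.84 and p53 targets one of 0.48 (adjusted p = 2.92e-06, 5.56e-05 and 8.42e-05, and 0.102, 0.102 and 0.168 with an estimated correlation). Antigen presentation, fatty acid synthesis, periportal genes and clock genes passed with adjusted p from 0.000227 to 0.00723. NRF2 targets, oxidative phosphorylation, urea cycle and amino acid genes, female-biased genes, neutrophil markers and ribosomal proteins passed with 0.00296 to 0.0159 and lost the call without 1 or more single libraries. The ribosomal protein list rose, with a mean log2 score of -0.25 at 7 weeks and -0.0819 at 16 weeks relative to fed wild types. Its direction was reversed without 7-week replicate 1 (adjusted p = 0.773), 7-week replicate 3 (0.75) or 16-week replicate 3 (0.151). With an estimated correlation these 10 lists had 0.102 to 0.811.

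Restricted wild types were set against wild types fed ad libitum, both at 16 weeks, to describe the answer of a normal liver to less food. Footprints on the major urinary protein gene Mup8 fell from 1667 ± 805 to 21.2 ± 18.3 CPM (SD, n = 4 each), 78.7-fold lower. Male-biased genes fell and female-biased genes rose. Of 82 ribosomal protein genes 63 rose and of 30 proliferation genes 15 fell, and both of these lists lost their call with an estimated correlation (adjusted p = 0.402 and 0.315). In all, 1483 genes changed, 664 up and 819 down, of which 274 and 359 changed more than 2-fold, and without restricted replicate 4 there were 939. A fit of the 8 compared libraries alone called 658, 324 up and 334 down. The excess of falls was absent with upper-quartile scaling (772 up and 768 down) and with a stricter filter on low counts (738 and 731).

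Fmo6 rose 196-fold in restricted wild types (log2 7.62 ± 0.46, adjusted p = 9.63e-11), and the leptin receptor Lepr 38.7-fold, to 277 ± 104 from 7.22 ± 2.96 CPM. The sulfotransferases Sult3a1 and Sult3a2 stood at 49.9 ± 48.1 and 11.8 ± 11.2 CPM against 0.0793 ± 0.0976 and 0.02 ± 0.04 CPM (adjusted p = 6.82e-06 and 2.17e-05), and Sqle rose 9.06-fold. The fed libraries hold too few counts of Sult3a1 and Sult3a2 for a fold, and without restricted replicate 2 their fitted log2 changes went from 8.87 to 8.08 and from 8.53 to 7.80. The largest falls, besides Mup8, were those of Mup14, Mup13, Mup1, the fatty acid elongase Elovl3 (log2 -5.89 ± 0.65, 59.3-fold lower) and the acute-phase gene Saa1. Without restricted replicate 2 Mup8 went from -6.30 to -6.98, Mup14 from -6.29 to -7.00, Mup13 from -5.24 to -6.02, Mup1 from -5.23 to -6.31 and Elovl3 to -6.95. The Mup1 call was lost in a fit of the 8 libraries alone, and the Saa1 call (adjusted p = 0.0208) in 3 of 8 fits without 1 library, with a log2 change of -3.32 in place of -5.23 and an adjusted p of 0.103 without ad libitum replicate 2. Igf1, Cdkn1a, Ercc1 and Gdf15 did not pass, with adjusted p from 0.769 to 0.959.

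Of 23 male-biased genes 19 fell under restriction in wild types (20 adjusted over the list alone), among them Cyp4a12a, at 80.3 ± 15.0 against 639 ± 44.0 CPM, and C6 (log2 -3.26 ± 0.20). The list held with an estimated correlation (adjusted p = 2.01e-46 and 0.000112). Of 29 female-biased genes 15 rose (18 adjusted over the list alone), such as Slc22a26 (log2 2.99 ± 0.29) and Cyp2a4 (1.51 ± 0.24), and held too (adjusted p = 9.97e-13 and 0.00857). Ribosomal protein genes rose, 63 of 82 (75 adjusted over the list alone), by 0.92 ± 0.17 for Rpl18 and 1.43 ± 0.26 for Rpl21 (adjusted p = 4.48e-33, and 0.402 with an estimated correlation). Of 38 translation factors 16 rose (24 adjusted over the list alone), with Eef1d and Naca as examples (adjusted p = 6.38e-09, and 0.402 with an estimated correlation). Of 30 proliferation genes 15 fell and 1 rose (19 and 1 adjusted over the list alone; adjusted p = 9.36e-11, and 0.315 with an estimated correlation). The replication helicase subunits Mcm5 and Mcm6 were at -3.76 ± 0.44 and -3.14 ± 0.42, and the tubulin Tubb5 was up.

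**Figure D2:**
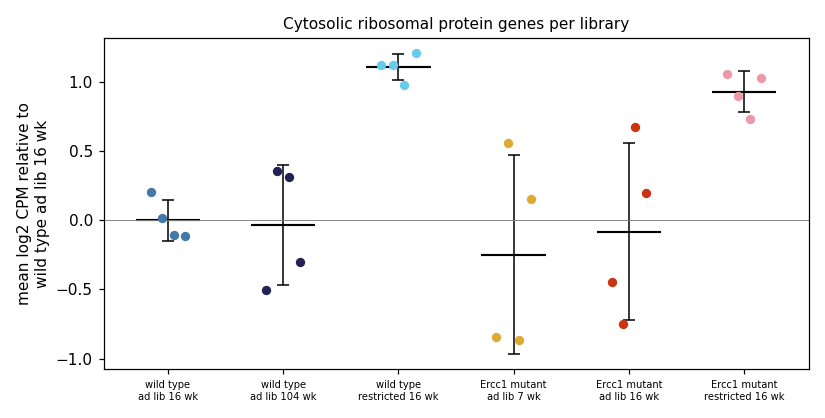
Mean log2 CPM of the ribosomal protein list per library (points), relative to wild types fed ad libitum at 16 weeks, with the group mean (line) and SD (bars, n = 4). Restricted wild types and restricted mutants lie at 1.11 and 0.931 on average, and the mutants fed ad libitum spread with SDs of 0.719 at 7 weeks and 0.638 at 16 weeks.

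Of 26 cholesterol synthesis genes 8 rose and 1 fell in restricted wild types (16 and 1 adjusted over the list alone; adjusted p = 1.06e-05, and 0.664 with an estimated correlation). Endothelial markers such as Stab2 had a median of 0.38, with 4 of 15 up (12 adjusted over the list alone). B and plasma cell markers had one of 2.20, macrophage markers one of 0.46 and stellate markers one of 0.58, with Igkc, Marco and Dcn up. Restricted replicates 3 and 4 carry 3 of these lists: the score per library was 0.771 and 0.777 in them against 0.00239 and 0.17 in replicates 1 and 2 for endothelium, 0.745 and 0.709 against 0.217 and -0.0321 for macrophages, and 0.656 and 0.837 against -0.376 and 0.144 for stellate cells. Exact permutation tests of these scores did not pass (p = 0.0857, 0.143 and 0.343). These 4 lists had adjusted p of 0.000198, 0.00174, 0.00228 and 0.00482, and 0.664, 0.402, 0.792 and 0.811 with an estimated correlation. Oxidative phosphorylation had a median of 0.16, with Cox7a1 up by 1.48 ± 0.33 (adjusted p = 0.00174, and 0.811 with an estimated correlation). Lists for the proteasome (Psmc3), erythroid cells (Alas2) and heat shock (Hspb1) passed at 0.0147, 0.0117 and 0.043, lost the call without single libraries, as did macrophages and stellate cells, and had 0.884, 0.57 and 0.884 with an estimated correlation.

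Restricted mutants were set against mutants fed ad libitum, both at 16 weeks, to describe the answer to restriction in the progeroid liver. Footprints on Elovl3, which elongates long fatty acids, fell from 94.2 ± 22.6 to 0.718 ± 0.327 CPM (SD, n = 4 each). Cyp2b10, a drug-metabolising enzyme low in ad libitum fed mutants, rose from 1.25 ± 1.04 to 50.4 ± 17 CPM, with a log2 change of 5.34, or 6.07 without ad libitum replicate 3. Every tested male-biased gene fell and most female-biased genes rose. Of 38 genes of amino acid breakdown 19 rose and of 77 of oxidative phosphorylation 31 rose, and both of these lists lost their call with an estimated correlation (adjusted p = 0.501 and 0.381). In all, 1420 genes changed, 682 up and 738 down, of which 303 and 287 changed more than 2-fold, and without restricted replicate 1 there were 933.

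Fmo6 was 179-fold higher (log2 7.48 ± 0.43, adjusted p = 7.15e-11). Sult2a2, Sult2a5, Sult3a1 and the glycogen targeting subunit Ppp1r3g stood at 5.93 ± 2.77, 5.4 ± 2.4, 16.9 ± 6.29 and 7.88 ± 14.2 CPM against less than 0.1 CPM on average. Restricted replicate 1 carries the level of Ppp1r3g, with 29.2 CPM against 0.17 to 1.8 CPM in the other 3, and without it the fitted log2 change went from 7.41 to 4.09. The ad libitum fed libraries hold too few counts of these 4 genes for a fold. The calls on Sult3a1 and Ppp1r3g were lost in limma-voom. Elovl3 was 128-fold lower and 5 major urinary protein genes fell with it, among them Mup14, 98.5-fold lower (log2 -6.62 ± 0.69, adjusted p = 3.16e-06), Mup8, Mup13, Mup15 and Mup12, at 54.7 ± 9.26 against 3233 ± 839 CPM. Igf1, Cdkn1a, Ercc1 and Gdf15 did not pass, with adjusted p from 0.49 to 0.946.

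All 23 male-biased genes fell in restricted mutants, also when adjusted over the list alone, with a median of -2.35 (adjusted p = 1.04e-58, and 2.04e-05 with an estimated correlation), as in Cyp4a12a (log2 -2.59 ± 0.17) and Nudt7 (-2.83 ± 0.22). Of 29 female-biased genes 22 rose and 1 fell (27 and 1 adjusted over the list alone), with a median of 2.39 (adjusted p = 7.08e-41, and 1.74e-05 with an estimated correlation). Cyp3a41b, 1 of them, went to 1003 ± 48.5 from 207 ± 27.8 CPM. Of 14 periportal genes 7 rose and 1 fell, in both counts, with Etnppl up by 2.79 ± 0.35 and arginase Arg1 by 0.93 ± 0.13 (adjusted p = 0.000374, and 0.0267 with an estimated correlation). Of 38 genes of the urea cycle and amino acid breakdown 19 rose and 3 fell (21 and 3 adjusted over the list alone; adjusted p = 3.1e-07, and 0.501 with an estimated correlation). Aass rose to 1344 ± 398 from 494 ± 19.4 CPM, and Ass1 rose too. Of 35 drug metabolism genes 13 rose and 6 fell (18 and 6 adjusted over the list alone), with Cyp2c39 at 783 ± 87.7 against 81.0 ± 7.45 CPM (adjusted p = 2.03e-07, and 0.127 with an estimated correlation).

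Of 77 oxidative phosphorylation genes 31 rose in restricted mutants (37 adjusted over the list alone), such as Cox7a1 (log2 1.93 ± 0.33) and Atp5c1 (adjusted p = 1.7e-09, and 0.381 with an estimated correlation). Ribosomal protein genes rose, 37 of 82 with 1 fallen (71 and 1 adjusted over the list alone), with Fau up by 1.09 ± 0.22, and 7 of 38 translation factors rose (9 adjusted over the list alone). These 2 lists had adjusted p of 1.16e-24 and 1.56e-05, and 0.518 and 0.615 with an estimated correlation. Cholesterol synthesis and the unfolded protein response had medians of -0.59 and -0.60, the second with Herpud1 and Sec61b down. Of 30 proliferation genes 8 fell, over all genes and adjusted over the list alone, with Mcm5 and Mcm6 at -2.54 ± 0.39 and -2.25 ± 0.39. The adjusted p of these 3 lists were 0.000161, 0.000249 and 0.000291, and 0.658, 0.794 and 0.615 with an estimated correlation. Targets of p53 such as Bax (log2 -1.02 ± 0.20) and Bbc3, antigen presentation genes such as B2m, gluconeogenesis with Got1 at 2209 ± 954 against 436 ± 30.2 CPM, and the genes encoded in mitochondria passed at 0.0051 to 0.0346. These 4 lists lost the call without 1 or more single libraries and had 0.596 to 0.794 with an estimated correlation.

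**Figure D3:**
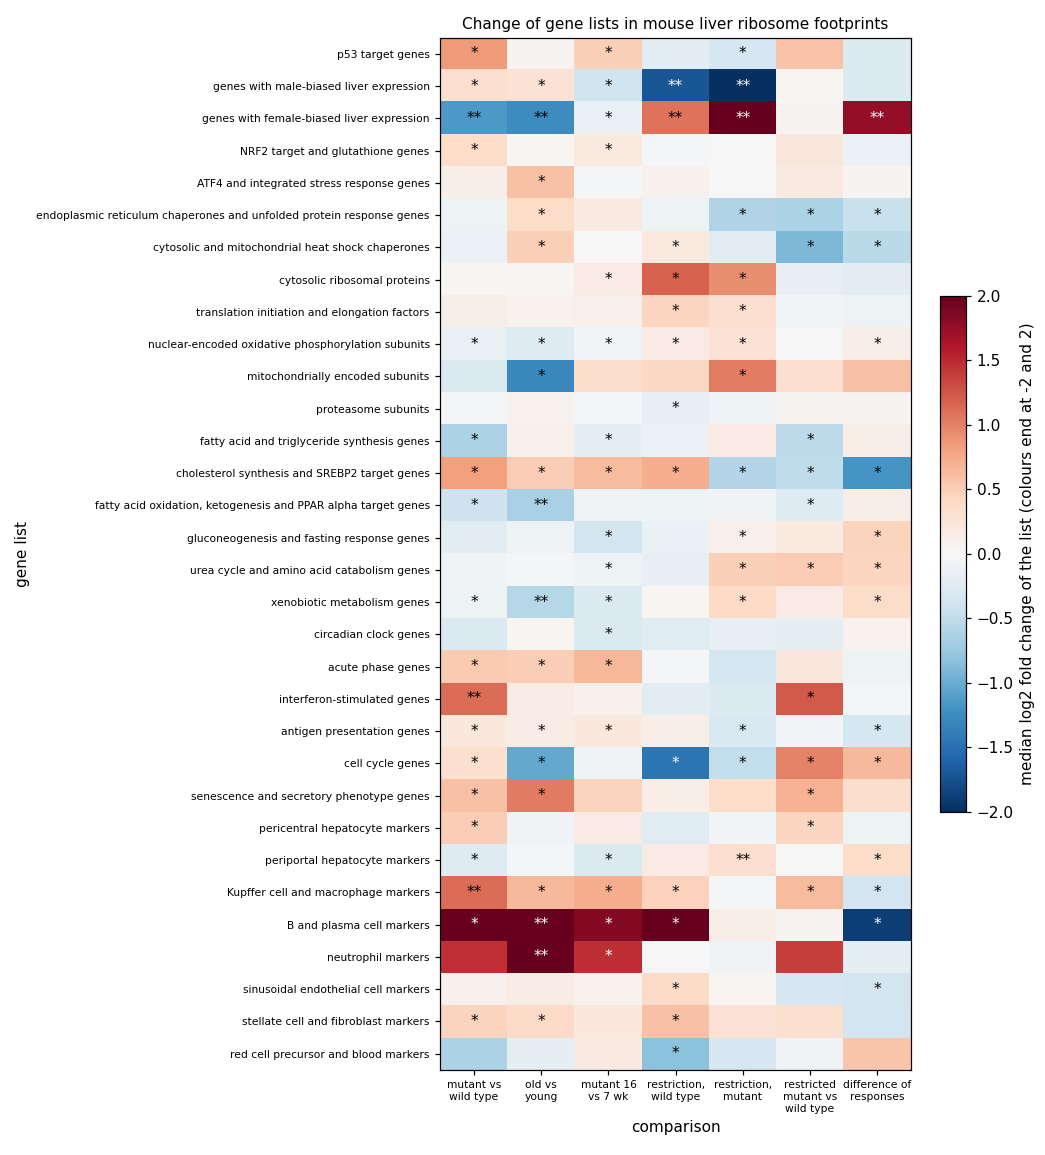
Median log2 change (colour, ending at -2 and 2) of 32 gene lists in the 7 comparisons, with 1 star for a camera adjusted p under 0.05 and 2 stars where an estimated correlation kept the call. The male-biased list is at -1.71 and -2.35 under restriction in wild types and mutants.

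Restricted mutants were set against restricted wild types to see which genotype differences exist under a restricted diet. Gpx6 stood at 31.0 ± 3.27 against 0.458 ± 0.203 CPM (SD, n = 4 each), and Afp, the fetal liver protein alpha-fetoprotein, at 19.9 ± 7.47 against 0.384 ± 0.348 CPM. Interferon response, amino acid breakdown and proliferation genes were higher in mutants and heat shock genes lower, but no list kept its call with an estimated correlation (0.444 to 0.661 for these 4). In the fit of all 24 libraries 2227 genes changed, 1146 up and 1081 down, of which 561 and 350 changed more than 2-fold. A fit of the 8 compared libraries alone called 769.

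Gpx6 was 70.5-fold higher (log2 6.14 ± 0.36, adjusted p = 1.4e-11) and Afp 47.0-fold (log2 5.55 ± 0.47, adjusted p = 2.42e-08), followed by Sult1e1, the ferritin receptor Scara5, the trehalase Treh and Slc13a5 with folds up to 29.8. Without restricted wild-type replicate 3 the log2 change of Sult1e1 went from 4.90 to 6.11 and that of Treh from 4.51 to 5.46, and without replicate 1 that of Scara5 from 4.54 to 5.18 and that of Slc13a5 from 4.25 to 5.19. Serpina12 was 10.4-fold lower, with Slc17a8, the taurine enzyme Csad, the cell cycle repressor E2f8 and A1bg also among the largest falls. A1bg varied most, at 6.81 ± 4.06 against 174 ± 230.3 CPM, and its call was lost in the fit of the 8 libraries alone. The change of A1bg went from -4.66 to -3.22 without restricted wild-type replicate 3, that of Csad from -3.18 to -2.40 without replicate 1 and that of E2f8 from -3.17 to -2.35 without replicate 2. Igf1, Cdkn1a and Gdf15 did not pass, with adjusted p of 0.218, 0.241 and 0.376.

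Of 35 interferon response genes 22 were higher in restricted mutants (25 adjusted over the list alone), with Usp18 at log2 3.66 ± 0.33 and Oas1a at 2.47 ± 0.28 (adjusted p = 4.78e-16, and 0.444 with an estimated correlation). Of 38 amino acid genes 18 were higher and 1 lower (20 and 1 adjusted over the list alone), such as Acmsd and Cth (log2 1.85 ± 0.22 and 2.08 ± 0.25; adjusted p = 9.93e-09, and 0.597 with an estimated correlation). Of 30 proliferation genes 11 were higher (14 adjusted over the list alone), with Mki67 and Top2a at 2.43 ± 0.44 and 2.12 ± 0.45 (adjusted p = 2.79e-06, and 0.597 with an estimated correlation). Of 21 heat shock genes 11 were lower (12 adjusted over the list alone), among them Fkbp4 (log2 -1.19 ± 0.17) and Stip1, partners of HSP90 (adjusted p = 1.03e-05, and 0.661 with an estimated correlation). Of 19 macrophage markers 9 were higher (10 adjusted over the list alone), with Mpeg1 and Cd5l as examples (adjusted p = 1.2e-05, and 0.597 with an estimated correlation).

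Of 37 fatty acid oxidation, ketogenesis and PPAR alpha target genes 14 were lower and 2 higher in restricted mutants (15 and 2 adjusted over the list alone; adjusted p = 6.66e-05, and 0.672 with an estimated correlation). Fabp1 was at log2 -2.02 ± 0.18 and Cd36 in the other direction at 2.73 ± 0.26. Of 24 fatty acid synthesis genes 8 were lower and 1 higher, in both counts, such as Dgat2 at -0.92 ± 0.13 (adjusted p = 0.000361, and 0.597 with an estimated correlation). Of 14 pericentral genes 6 were higher, over all genes and adjusted over the list alone, among them Oat and Rhbg at 1.45 ± 0.21 and 2.98 ± 0.48 (adjusted p = 0.0017, and 0.597 with an estimated correlation). The unfolded protein response and cholesterol synthesis had medians of -0.64 and -0.51 (adjusted p = 0.00171 and 0.0052, and 0.383 and 0.163 without restricted wild-type replicate 3), with Tm7sf2 and Stard4 lower. The senescence list, with Mmp12 at 3.77 ± 0.62, passed at 0.0428 and lost the call in 5 of 8 fits without 1 library. With an estimated correlation these 3 lists had adjusted p of 0.794, 0.776 and 0.727.

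The interaction asked which genes answered restriction differently in mutants and wild types. Cd36, a fatty acid transporter, fell in wild types from 138 ± 46.5 to 30.6 ± 5.51 CPM and rose in mutants from 78.6 ± 11.2 to 203 ± 14.3 CPM (SD, n = 4 each). Sqle, a sterol enzyme, rose in wild types from 2.74 ± 1.77 to 26 ± 13.4 CPM and stood at 47.8 ± 7.21 and 27.7 ± 8.13 CPM in mutants. The test called 98 genes, 63 with a more positive and 35 with a more negative response in mutants, and 1552 had an unadjusted p under 0.05. DESeq2 called 279. The edgeR count was 63, 64 and 65 without mutant ad libitum replicate 4, restricted mutant replicate 1 or wild-type ad libitum replicate 3, and 204 and 177 without restricted wild-type replicates 1 and 2.

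Among the more positive responses the difference was 3.55 ± 0.36 for Cd36 (adjusted p = 1.13e-05), and 3.75 ± 0.57 for the bile acid transporter Slc10a2 (adjusted p = 0.00165). Cyp2b10 was at 3.55 ± 0.57 (adjusted p = 0.00239), with Cyp2b13, Cyp2b9 and Treh between 3.45 and 3.54. Without ad libitum mutant replicate 3 Cyp2b10 was at 4.26, and without restricted wild-type replicate 3 Treh was at 4.39. Under restriction Cyp2b10, Cyp2b13 and Cyp2b9 still had lower means in mutants (50.4, 103 and 261 CPM) than in wild types (171, 285 and 611 CPM). In ad libitum fed mutants they had 1.25, 2.42 and 8.39 CPM, against 49.4, 77.6 and 224 CPM in fed wild types. Slc10a2 fell in wild types from 59.2 ± 15.2 to 2.20 ± 0.921 CPM and stood at 30.8 ± 6.58 and 15.1 ± 9.26 CPM in mutants. Among the more negative ones the NRF2 target Osgin1 had a difference of -2.57 ± 0.40 (adjusted p = 0.00165). It had 61.4 ± 10.0 and 73.6 ± 22.8 CPM in wild types and 199 ± 51.8 and 40.2 ± 4.54 CPM in mutants. The aldolase Aldoc had one of -1.75 ± 0.27 (adjusted p = 0.00146), from 4.86 ± 1.34 and 14.5 ± 3.14 CPM in wild types and 18.5 ± 2.33 and 16.2 ± 1.88 CPM in mutants. Sqle (-3.96 ± 0.86, adjusted p = 0.0316), Msmo1, Dnajc12 and Cyp51 passed as well and lost the call in 9, 11, 10 and 8 of the 16 fits without 1 library, with adjusted p up to 0.0801, 0.0872, 0.0878 and 0.0781.

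**Figure D4:**
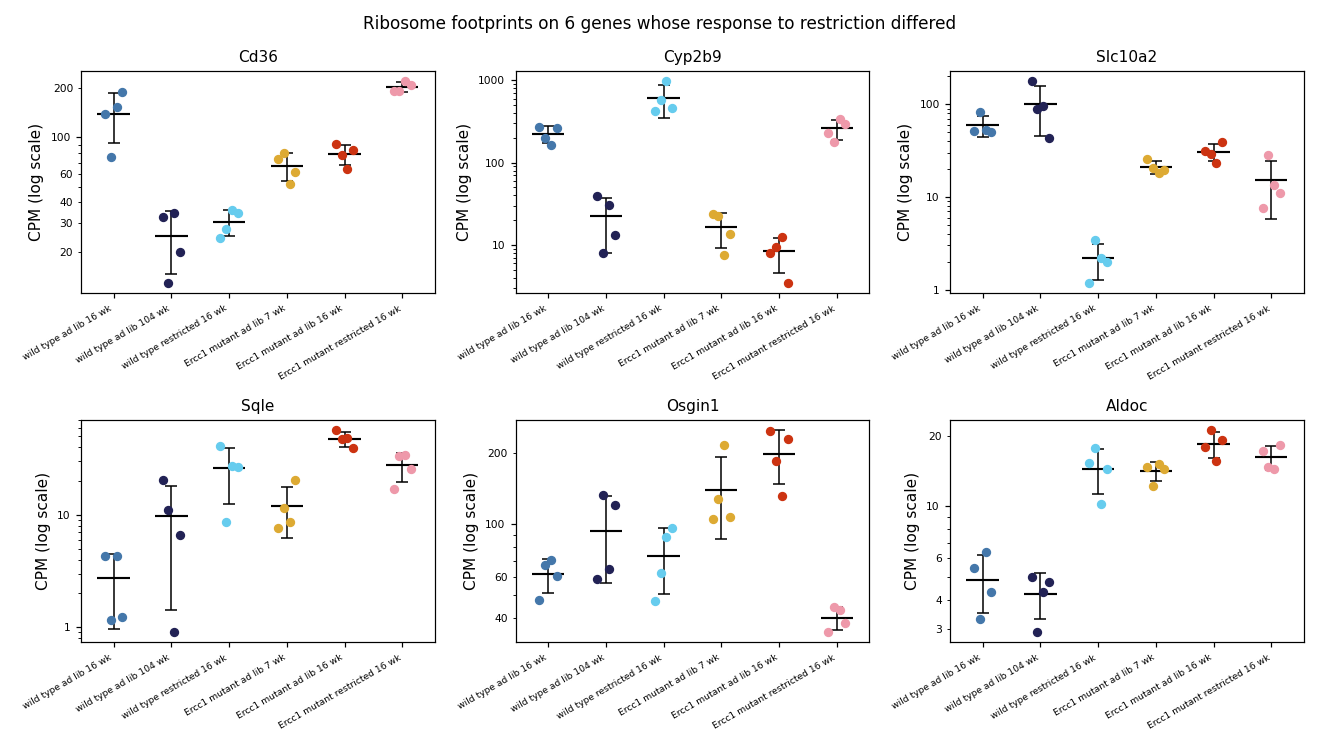
CPM on a log scale per library (points) of 6 genes whose response to restriction differed between genotypes, in the 6 groups, with the group mean (line) and SD (bars, n = 4). Cd36 goes from 138 to 30.6 CPM in wild types and from 78.6 to 203 CPM in mutants.

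Of 29 female-biased genes 7 responded more positively in mutants and 1 more negatively (11 and 1 adjusted over the list alone), with Cyp3a41b at 2.24 ± 0.35 and Cyp2c69 at -1.60 ± 0.26. This list kept its call with an estimated correlation (adjusted p = 2.54e-11 and 0.032). Its mean log2 score per library, relative to fed wild types at 16 weeks, overlapped under restriction. It was 1.27 to 2.02 in restricted wild types and 1.56 to 1.88 in restricted mutants. Fed mutants at 16 weeks had -1.32 to -0.995 and fed wild types -0.161 to 0.0785, so the genotypes differed mainly in the fed state. Of 26 cholesterol synthesis genes 4 responded more negatively over all genes and 20 adjusted over the list alone, with a median difference of -1.18 (adjusted p = 1.7e-19, and 0.101 with an estimated correlation). Tm7sf2 was at -1.05 ± 0.23 (adjusted p = 0.0205, and 0.053 without wild-type ad libitum replicate 3). Of 38 amino acid genes 3 responded more positively (14 adjusted over the list alone), with Aass at 1.53 ± 0.27 and Cth at 1.76 ± 0.35 (adjusted p = 3.19e-12, and 0.16 with an estimated correlation). Of 35 drug metabolism genes 6 did so over all genes (9, and 1 more negative, adjusted over the list alone; adjusted p = 9.24e-08, and 0.122 with an estimated correlation). Cyp2c39 and Cyp2c29 led it at 2.32 ± 0.26 and 2.51 ± 0.30. Gluconeogenesis and periportal genes had median differences of 0.45 and 0.37, the second with Etnppl at 3.11 ± 0.48 (adjusted p = 0.000765 and 0.00231, and 0.258 and 0.101 with an estimated correlation). Heat shock genes, macrophage markers, B and plasma cell markers and antigen presentation had median differences of -0.53, -0.38, -1.88 and -0.35 (adjusted p from 2.61e-05 to 0.00155, and 0.206 to 0.567 with an estimated correlation). Proliferation, the unfolded protein response, oxidative phosphorylation and endothelial markers passed at 0.00155 to 0.0188 and lost the call without 1 or more single libraries and with an estimated correlation (0.723 to 0.929).

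Long and short genes were compared because unrepaired DNA damage stops transcription more often in long genes. Among 11984 genes, the log2 CPM of genes of at least 68.4 kb minus that of genes of at most 8.46 kb was -0.674 ± 0.110 in ad libitum fed mutants and -0.525 ± 0.0607 in wild types at 16 weeks (SD, n = 4 each). The difference of -0.148 did not pass an exact permutation test (p = 0.0857, adjusted p = 0.343 over 6 comparisons). The other 5 comparisons had differences from -0.159 to 0.104 with adjusted exact permutation p from 0.343 to 0.486, and the smallest unadjusted p that 4 against 4 libraries can give is 0.0286. A single comparison at that value could not pass the adjustment over 6 comparisons, so the absence of a trend is not shown.

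The log2 changes of mutants and of old wild types, both against young wild types, correlated across genes at r = 0.392, with a covariance of 0.173. Genes are not independent replicates, and groups simulated without change, the shared one included, gave r = 0.491 and a covariance of 0.0607. The 2 comparisons shared 145 rises and 159 falls, against 33.0 and 28.3 for independent lists, with 12 and 9 genes called in opposite directions. Since both use the young wild types, independent lists are not the right base for these counts. With the young wild types split into 2 and 2 libraries r averaged 0.276, with 26.2 rises and 64.7 falls shared and 5.17 and 3.5 genes in opposite directions on average. The simulated groups shared 0 calls, but no gene was changed in them, so they give no base for shared calls. Restriction in mutants and in wild types, which share no library, correlated at r = 0.582 and shared 220 rises and 314 falls, against 37.1 and 49.5 for independent lists. The mutant change and its answer to restriction share the ad libitum fed mutants and correlated at r = -0.162, against -0.505 in simulation and -0.0611 on average with those libraries split. Of their calls 91 and 94 went in opposite directions and 43 and 61 in the same direction, against 38.5 and 37.2 and 19 and 23.2 on average with the libraries split. The 0 shared calls in simulation give no base here either. The course of the mutants and natural ageing, which share no library, correlated at r = 0.172. They shared 8 rises and 6 falls, against 1.43 and 1.06 for independent lists, with 2 and 3 genes called in opposite directions.

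P-sites on ORFs changed in the same comparisons. Of 18344 tested ORFs 1677 changed in ad libitum fed mutants, 1525 in old wild types, and 87 in the course from 7 to 16 weeks. Restriction changed 1982 ORFs in wild types and 1793 in mutants, with 3114 in restricted mutants against restricted wild types and 120 in the interaction. Of all tested ORFs 447, with a median of 31 codons, lie before the most counted ORF of their transcript. Among these, 62 were lower and 7 higher in restricted mutants than in restricted wild types, against 1547 lower and 1567 higher of all ORFs. The excess of lower ORFs was not limited to this place. After the most counted ORF 13 were lower and 5 higher, and of those overlapping it 15 were lower and 6 higher. With restriction in mutants 27 ORFs before the most counted one fell and 6 rose, with 7 and 1 after it and 14 and 2 overlapping it. Before it 9 fell and 5 rose in restricted wild types. Against young wild types 17 of those before it fell and 2 rose in ad libitum fed mutants, and 13 fell and 6 rose in old mice. The ratio of upstream to most counted ORF passed in no comparison (smallest adjusted p 0.0857).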

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

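The tests of technical explanations for the 3 patterns below and the limits set for the other splits of the libraries were chosen after the results had been seen, and the search for single libraries that stand apart and the interaction term were planned. For the interaction the draws of splits were raised from 60 to 100 after the 60 had been seen.

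Other splits of the same libraries were used to ask how often a split by chance gives as many genes. Each time the compared libraries alone were fitted, so the counts differ from those above. In 5 comparisons only the real split, 1 of 35, gave as many genes. This is the smallest share that 35 splits can give, with no correction over the comparisons. The other splits mix the 2 groups, so a real difference widens their spread and lowers their counts. Chance is made less likely for these 5 comparisons but is not excluded. The real and the highest other counts were 2195 and 1 for mutants against wild types, 1370 and 1 for old against young, and 687 and 3 for restriction in wild types. They were 1274 and 1 for restriction in mutants, and 791 and 7 for restricted mutants against restricted wild types. Between 7 and 16 weeks in mutants the real split gave 448 genes, again 1 of 35, and the highest other 108, and the same limits hold. That other split points to a structure of the samples: it sets replicates 1 and 3 at 7 weeks with replicates 1 and 2 at 16 weeks, and all 108 genes were lower in these. Of the 108 genes, 70 are on the ribosomal protein list and 10 on the translation factor list.

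For the interaction 3 of 100 drawn splits, the real one included, gave as many genes as the real split, a share of 0.03, while the share was 0.05 in the first 60. Whether the share lies under 0.05 therefore rests on the number of draws, and chance is not excluded. The real split gave 66 genes, and the others at or above it 515 and 190. The first puts 7 of 8 wild types on 1 side of the contrast and the second 7 of 8 mutants, near the genotype split, so both point to a structure of the samples.

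Single libraries stood apart from the other 3 of their group, by a gap to the nearest that took most of the range of the group, in 18 of 232 groups of values tested, where chance gives 1 in 20. None of the 30 groups of whole-library measures was among them. In young wild types they were Gpx6 at 0.47 CPM in replicate 1 (others 0.0827 to 0.123), and Saa1 at 898 (30.2 to 139) and Slc10a2 at 82 (50.8 to 53) in replicate 2. Sult3a2 was at 0.08 in replicate 3 (others at 0), and Cyp2b19 at 10.6 in replicate 4 (6.7 to 7.32). Old replicate 3 had Socs3 at 25.9 (8.26 to 10.9), and restricted wild-type replicate 2 had E2f8 at 18.5 (2.73 to 5.37). In mutants at 7 weeks they were Cdkn1a at 44.3 (27.4 to 29) and Gdf15 at 6.57 (2.01 to 2.59) in replicate 1. Replicate 3 had Cyp4a12a at 838 (619 to 638) and Cyp4a12b at 723 (532 to 542), and replicate 4 had Tmem43 at 9.97 (6.12 to 6.42). In mutants at 16 weeks they were Mup13 at 1300 (627 to 692) and Rgs16 at 9.96 (5.9 to 6.57) in replicate 1, and Cib3 at 12.9 (5.27 to 6.02) in replicate 2. Restricted mutants had Ppp1r3g at 29.2 (0.17 to 1.8) and Cyp2b10 at 75.7 (38.8 to 45) in replicate 1, and Gdf15 at 6.9 (1.43 to 2.15) in replicate 2.

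The response to restriction differed between mutants and wild types, by the interaction term, in 12 genes named by the rule on size. Given as the log2 difference of the 2 responses, with the wild-type and the mutant response in brackets, they were Slc10a2 at 3.75 (-4.77 and -1.03), Cyp2b10 at 3.55 (1.79 and 5.34), Cd36 at 3.55 (-2.18 and 1.37) and Cyp2b13 at 3.54 (1.88 and 5.42). Cyp2b9 had 3.51 (1.45 and 4.96) and Treh 3.45 (-2.26 and 1.19). On the other side were Sqle at -3.96 (3.18 and -0.78), Osgin1 at -2.57 (0.26 and -2.31) and Msmo1 at -2.40 (1.14 and -1.26). Dnajc12 had -2.30 (0.82 and -1.48), Cyp51 -1.81 (1.04 and -0.78) and Aldoc -1.75 (1.56 and -0.19).

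Footprints on ribosomal protein genes varied between libraries of 1 group, with an SD of the log2 score of 0.719 and 0.638 in mutants fed ad libitum at 7 and 16 weeks against 0.149 in young, 0.431 in old and 0.0935 in restricted wild types and 0.15 in restricted mutants. The following 4 relations are correlations of deviations from group means over 24 libraries with 100000 permutations, and r is also given without the 2 libraries farthest from their groups by this score, 7-week mutant replicate 2 and 16-week mutant replicate 3. Library total (r = 0.0426, p = 0.805, rho = 0.0478 with p = 0.805, adjusted p = 0.805 for both, 0.0154 without the 2) and, as a sign of a bias to short genes, the oxidative phosphorylation score (r = -0.136, p = 0.524, rho = -0.137 with p = 0.551, adjusted p = 0.699 and 0.735, -0.184 without the 2) did not follow the score by the bounds set. Reads shared with ribosomal protein pseudogenes would not carry 4 elongation factors along, yet their median followed it (r = 0.938, rho = 0.933, p = 1e-05 for both, the smallest that the permutations can give, adjusted p = 4e-05, 0.92 without the 2). The 10 translation factors assigned a 5' oligopyrimidine tract from general knowledge after the data were seen had r of 0.656 to 0.978, and they include the 4 elongation factors above. The 28 others had r of -0.447 to 0.969 and were not shown to lack such a tract, among them Tpt1 (0.969) and Rack1 (0.965). The difference of median r was 0.707 (permutation p = 0.0117, rho difference 0.67 with p = 0.0154, adjusted p = 0.0235 and 0.0308, 0.716 without the 2). Since the genes were assigned with the data in view, this difference does not test control through the tract, which stays a hypothesis. Footprints alone cannot separate mRNA level and translation.

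Male-biased genes fell and female-biased genes rose under restriction in mutants. Reads shared between paralogs of the large families, such as Cyp and Mup, would leave genes outside these families unmoved. Yet 7 of 7 such male-biased genes fell (median log2 change -2.72) and 7 of 12 female-biased ones rose (median 2.26), none of these going the other way. The genes were set apart by family name alone, and some, such as Slc22a26 and Slc22a27, may share reads with paralogs of their own. In wild types the medians were -1.64 (5 of 7 fell) and 0.84 (3 of 12 rose), and the second lies under the bound of 1 that was set. A larger share of albumin would lower all other genes alike, by a log2 value of -0.109 in mutants, but the mean of the female-biased genes rose against that of the male-biased ones by 5.51 (exact p = 0.0286, the smallest possible). What drives the pattern was not tested, and an effect of the diet itself and the time since the last meal stay open.

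Macrophage markers rose by a log2 score of 1.19 in mutants against wild types at 16 weeks, with an exact p = 0.0286, the smallest possible, and in each of the fits that leave out 1 library the rise was at least 1.11. A lower share of hepatocytes would raise markers of other cell types alike, but the endothelial score moved by 0.0676 (exact p = 0.514) and the difference of the 2 rises was 1.12 (exact p = 0.0286). Stellate, neutrophil and B and plasma cell scores rose by 0.47, 1 and 1.55 (exact p = 0.0286 each) and the cholangiocyte score by 0.175 (exact p = 0.257). These values are consistent with more macrophages or with more expression of these markers per macrophage in mutant liver, and footprints of whole liver cannot separate the 2.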

How the results depend on the processing

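The tests with the ribosomal protein score as covariate and without 2 picked libraries (old wild-type replicate 1, lowest in P-sites per count, and restricted wild-type replicate 4, farthest from its group along the first component, picked by rank without a test) were chosen after the data had been seen, and the other alternatives were planned.

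Counts of genes past the threshold moved by more than 1.5 times under few settings. With only the compared groups in the fit they were 2138 for mutants against wild types (1310 with all groups), 436 between 7 and 16 weeks in mutants (53), 658 for restriction in wild types (1483) and 769 for restricted mutants against restricted wild types (2227). Of the 1310, 53, 1483 and 2227 genes this kept 1232, 51, 615 and 749. This setting also estimates the spread from 8 libraries in place of 24, and which part of it moves the counts was not tested. Both counts that fell use the restricted wild types, whose libraries correlated least with each other (r = 0.944 to 0.967). Those that rose compare groups whose libraries correlated at 0.971 to 0.985. With 1 spread for all groups, the main counts may be too high for the first and too low for the second. DESeq2 gave 167 genes between 7 and 16 weeks and 279 for the interaction (98), and kept all 53 and all 98. For the 7 to 16 week comparison the library number as covariate gave 82 and leaving out the 2 picked libraries gave 103, and the cause was not tested. With the ribosomal protein score as covariate restriction gave 458 genes in wild types, of which 427 of the 1483 were kept, and 605 in mutants (1420), of which 572 were kept. The score goes with the diet, so this drop is no evidence against an effect of restriction.

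Leaving out each library in turn gave 813 (without 16-week mutant replicate 1) to 1096 genes for mutants against wild types, and 861 without wild-type replicate 4. For old against young it gave 743 (without young replicate 4) to 1049. Between 7 and 16 weeks in mutants it gave 18 (without 7-week replicate 1 or 3) to 43, with 23 without 7-week replicate 2 or 16-week replicate 1 and 22 without 16-week replicate 4. Restriction gave 939 (without restricted replicate 4) to 1866 in wild types and 933 (without restricted replicate 1) to 1467 in mutants. The genotype difference under restriction gave 1851 to 2221 genes, within 1.5 times of 2227. The interaction gave 63 (without 16-week mutant replicate 4) to 204 (without restricted wild-type replicate 1), with 64 without restricted mutant replicate 1, 65 without young wild-type replicate 3 and 177 without restricted wild-type replicate 2.

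Gene lists depended most on how the correlation between genes was treated. With an estimated correlation the lists past the threshold were 3 for mutants against wild types (19 with the preset), 5 for old against young (18), 0 between 7 and 16 weeks (18) and 2 and 3 for restriction in wild types and mutants (14 and 15). They were 0 for restricted mutants against restricted wild types (11) and 1 for the interaction (14). With the ribosomal protein score as covariate there were 9 for restriction in wild types. Leaving out libraries gave 14 to 21, 15 to 20, 14 to 21, 13 to 15, 12 to 17, 9 to 14 and 12 to 17 in the same order.

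The ribosomal protein list, which rose between 7 and 16 weeks in mutants with all libraries, is not stable. Its adjusted p ran from 1.2e-14 without 7-week replicate 2 to 0.773 without 7-week replicate 1. The direction was reversed without 7-week replicate 1 (0.773) or 3 (0.75) and without 16-week replicate 3 (0.151), and without 16-week replicate 4 it was 0.223. It was 0.162 with only the compared groups, 0.652 with the score as covariate and 0.811 with an estimated correlation.

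The correlation of the changes in mutants and in old liver was 0.276 as a mean over splits of the shared libraries, against 0.392 with all of them on both sides. For mutants against wild types and restriction in mutants it was -0.0611 against -0.162. Shared libraries push such a correlation up in the first case and down in the second by construction. Leaving out libraries gave 0.369 to 0.435 and -0.206 to -0.125.

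The replicate block gave 1250, 1096, 60, 1398, 1335, 2149 and 112 genes in the order used above. Libraries with the same number in different groups did not pair: over 60 such pairs the mean correlation of deviations from the group means was 0.00707, against -0.00218 for different numbers.

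Scaling by RLE or upper quartiles moved the median of all genes by less than 0.05. Over all settings and results, each counted once per setting, 872 calls were lost and 236 results that had not passed were called. A further 3 reversed their direction, and 35 counts or values without a test moved. Of the changed genes that the naming rule picks, 63 of 81, 54 of 71, 9 of 23, 53 of 77, 57 of 70, 67 of 74 and 17 of 27 kept the call without each single library. P-site counts per gene and the exonic length of genes were not run, because the deposited ORF table names no genes and the annotation at hand holds no exons.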

Other observations

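The tests on upstream ORFs were chosen after the data had been seen, and the lists and the genes given here come from planned tests.

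Of 19 clock genes 3 rose, 4 fell and 12 were not called in old liver (camera adjusted p = 0.652). Nr1d1 had a log2 change of 3.68 ± 0.43 (adjusted p = 5.11e-06, and 4.36 without young replicate 1) and Dbp one of 2.96 ± 0.36 (adjusted p = 8.25e-06), while Cry1 had -1.97 ± 0.21 (adjusted p = 6.18e-07). The hour of collection was not tested as an explanation. Igfbp2, a binding protein of insulin-like growth factors, rose by a log2 change of 1.39 ± 0.27 in mutants (adjusted p = 0.00155), and by 2.74 ± 0.28 in wild types (adjusted p = 8.04e-07) and 1.10 ± 0.27 in mutants (adjusted p = 0.00879) under restriction. The growth hormone receptor Ghr changed by -0.88 ± 0.17 in wild types (adjusted p = 0.000809) and -1.08 ± 0.17 in mutants (adjusted p = 6.77e-05) under restriction. Igfbp2 and Ghr belong to the list of the somatotropic axis, which passed in no comparison.

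Of 27 targets of ATF4 3 rose, 3 fell and 21 were not called in mutants (camera adjusted p = 0.661), with Asns at 3.49 ± 0.55 (adjusted p = 0.000107), Vldlr at -3.83 ± 0.48 (adjusted p = 5.56e-06) and Atf5 at -1.46 ± 0.31 (adjusted p = 0.00251). Among genes of nucleotide excision repair Ercc2 had -1.04 ± 0.20 in mutants (adjusted p = 0.00102), next to Ercc1 itself. Ercc3 had 0.67 ± 0.13 in restricted mutants against restricted wild types (adjusted p = 0.000662).

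The lists that passed in none of the 7 comparisons were mitochondrial ribosomal proteins (smallest adjusted p 0.0916), bile acids (0.177), nucleotide excision repair (0.346), lysosome (0.234), the somatotropic axis (0.0702) and cholangiocytes (0.25). Markers of T and NK cells, pancreas and adipocytes had 1, 2 and 4 genes left, too few to test.

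The ratio of P-sites on upstream ORFs to those on the main ORF of the same transcript, over 444 pairs, differed by a log2 value of -0.373 between restricted mutants and restricted wild types (exact p = 0.0571, adjusted p = 0.114). It fell by 0.186 in mutants against wild types and by 0.24 under restriction in mutants (exact p = 0.0286, the smallest possible, adjusted p = 0.0857 for both), and none of the 3 passes the correction. Since the smallest possible p did not pass either, the correction leaves the question undecided. The group means were -2.87 ± 0.246 in restricted wild types, -3.24 ± 0.104 in restricted mutants, -2.81 ± 0.103 in young wild types and -3 ± 0.0462 in mutants at 16 weeks (SD, n = 4 each). Since no difference passed, none is taken as established. Less initiation upstream and a different share of footprints lost in the short ORFs were not tested and could not be told apart with these few libraries.

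Footprints on mitochondrial genes took 0.305 ± 0.151% of the counts in young wild types, 0.119 ± 0.0686% in old ones, 0.42 ± 0.132% in restricted wild types, 0.2 ± 0.0465% and 0.271 ± 0.105% in mutants at 7 and 16 weeks and 0.588 ± 0.442% in restricted mutants (SD, n = 4 each). Replicate 1 of the restricted mutants had 1.23%, and without it their mean was 0.373%, while restricted wild types without their own highest library, replicate 1 at 0.608%, had a mean of 0.357%.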
